A study of Mus musculus with 2 samples.

How the data were processed

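Single cells of healthy adult mouse urethra were profiled with 10x Genomics droplet chemistry in 2 libraries that form 1 group. Replicate 1, called library 1 here, held cells of 1 mouse, and replicate 2, called library 2, held pooled cells of 2 mice. Per the labels' protocols, tissue was digested for 1 h in cold protease at 10 mg/mL, about 17400 cells were loaded per library, no magnetic sorting was used, and reads of a NextSeq and a NovaSeq instrument were combined per library. The labels name v2 and v3 3' kits without saying which library used which. The libraries come from different animals and differ in depth, and the labels do not say whether the kit differed as well.

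The deposited matrices hold raw UMI counts, whole numbers of unique molecular identifiers per gene and cell barcode, made by the authors with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. The files are of the filtered kind, so barcodes without cells had been removed before deposit. The gene annotation is not given in the sources used here. Of the 31053 gene identifiers, 30934 (99.6%) were found in GENCODE vM21, which uses the mm10 assembly and from which coordinates were taken. Library 1 held 15027 barcodes with 35686741 UMIs, and library 2 held 14304 barcodes with 161505367 UMIs. A share of cells has an exact Clopper-Pearson 95% interval, and a share of 0 has an upper limit of 3 cells. Both cover counting error only.

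Cells with 500 or more genes and a mitochondrial share of at most 20% were kept. In library 1, 2860 barcodes had fewer genes and 386 exceeded the mitochondrial limit, and in library 2 the numbers were 744 and 2050. Scrublet was run per library with an expected doublet rate of 10%. Its automatic threshold marked 0% of cells in both libraries, so the rule set beforehand for that case was used and the top 8% of scores were removed, 985 and 963 cells. The number removed is therefore fixed by that rule and does not measure how many doublets there were. Counts were scaled per cell and log-transformed in scanpy 1.11.5 with anndata 0.12.19, 2000 variable genes were scaled within library, and 30 principal components and 15 neighbours fed a shared-neighbour graph that leidenalg 0.10.2 and igraph 0.11.9 partitioned at resolution 1.0. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

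Cell classes were named from markers of 26 classes fixed before the data were examined, as were the comparisons, the alternatives and 28 gene lists with 417 genes, of which 416 are in the files. List genes were kept out of the variable genes, so they did not enter the clustering themselves. List genes that vary along with the clustering genes or the class markers are still tied to how the classes were defined. The scoring rule that turns markers into names went through 5 versions while cluster markers were inspected, before any comparison between classes was run. In its last version a marker counts for a cluster at 2-fold or more over the median cluster, at 50 CPM or more, and at 25% or more of the highest cluster of the library. A name needs 3 or more such markers and no larger number of another class's markers among the 10 leading genes. A shallow cluster without its own markers among those 10 stays unnamed, as does a cluster in which another class also reaches 3 markers and none of its own lead. Of 34 clusters, 23 were named and 11 were not. Unnamed clusters that share their leading genes across the libraries were joined for shares. Unnamed clusters were placed in the epithelial compartment when Epcam was at 2-fold or more of the fibroblast-like level, and those in which several classes of 1 compartment reached 3 markers were placed in that compartment. A shallow unnamed cluster, with a median UMI count under 1/3 of that of its library, was placed in none. This kept out cluster 5, whose Epcam (450.1 CPM) was over 2-fold of the mean fibroblast-like level (215.7 and 78.8 CPM in clusters 9 and 15).

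Raw counts were summed per library and class, and classes were compared in R 4.3.3 with edgeR 4.0.16, using its quasi-likelihood test on 4 sums per comparison, TMM normalization, the filterByExpr filter and library as a block. Both classes of a comparison come from the same animals, so the libraries pair them by design. This leaves 1 residual degree of freedom, and p-values lean on the spread shared across genes. Each library comes from different mice, but with 2 libraries that spread includes the technical difference between them. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR, an absolute log2 fold change of 1 or more and the same direction in both libraries. Classes needed 30 or more cells in each library. Of 5 planned comparisons 3 could be run. Prostate secretory epithelial-like and urothelial umbrella-like cells were under that minimum in library 1. Another 3 comparisons were chosen after the classes were seen. The standard error of a log2 fold change is its size over the square root of the F statistic. Clusters were defined on the same counts that were then tested, so the total numbers of called genes include genes that shaped the clusters.

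Up to 3 called genes per list are named, those with the largest absolute log2 fold change among genes with a mean of 10 CPM or more in the higher class. Not every gene that this rule names is given in the text or figures. For a gene with 0 counts in a class in both libraries, the fold is a lower bound against 3 counts over both libraries. With 1 to 3 counts, the ratio of pooled CPM is given with its 95% counting interval. For 8 signalling lists, a gene was given to a class when that class had the highest CPM in both libraries, at 20 CPM or more and at 2 or more times the next class, among the 10 named classes with 30 or more cells in each library. Between libraries, genes were named when they differed 4-fold or more in the same direction in every class with 100 or more cells in each library, with counts under 3 set to 3. The 5 largest per direction by median log2 ratio are named.

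The edgeR step was tested on simulated counts with 200 changed genes. Changed genes were counted at an adjusted p under 0.05 in the right direction, without the fold minimum, and unchanged genes by the full rule for a call. In the comparison of luminal with basal cells (13205 genes), 100 of 100 genes changed 4-fold and 74 of 100 changed 2-fold were counted, and 2 unchanged genes were called. The median absolute log2 fold change of the genes changed 2-fold was 0.95 there, under the minimum for a call. In the comparison of fibroblasts with smooth muscle (7965 genes), the numbers were 99 of 100, 51 of 100 and 0. The simulation assumed a dispersion of 0.02. Only genes above a minimum expected count were changed. Apart from these, both classes had the same profile within each library. The numbers therefore do not measure recovery or false calls in the real data, where a class can come from different clusters in each library. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, no replicate block, all classes in 1 fit, 200 or more genes per cell, a mitochondrial share of at most 10%, no doublet removal, resolutions 0.5 and 2, separate clustering of each library, count splitting (clustering and testing on separate binomial parts of each count) and each library left out.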

Results

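The urethra of healthy adult mice was dissociated and its cells were profiled by single-cell RNA sequencing in 2 libraries of 1 group, with no treatment to compare. Library 1 came from 1 mouse and library 2 from 2 pooled mice. Library 1 held 35686741 UMIs (unique molecular identifiers, each marking 1 captured RNA molecule) in 15027 barcodes, with a median of 1781 UMIs and 827 genes per barcode. Library 2 held 161505367 UMIs in 14304 barcodes, with medians of 8184 UMIs and 2603 genes. After filtering, 11083 cells (73.8%) of library 1 and 10986 cells (76.8%) of library 2 were kept, with medians of 2039 and 9433 UMIs. Y-linked transcripts were present in both libraries: Ddx3y was at 69.0 CPM in library 1 and 51.8 CPM in library 2, Eif2s3y at 56.6 and 48.8 CPM, Uty at 30.23 CPM in library 1 and 19 CPM in library 2, and Kdm5d at 18.0 and 18.8 CPM. Xist, the RNA of the inactive X chromosome, had 44 UMIs (1.43 CPM) in library 1 and 40 UMIs (0.282 CPM) in library 2. The labels describe the tissue and its dissociation and state no hypothesis, so the comparisons the design allows are between cell classes of the same libraries.

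Epithelial cells made up most of the tissue preparation. They were 82.63% of kept cells in library 1 (95% exact Clopper-Pearson interval 81.91 to 83.33) and 76.26% in library 2 (75.45 to 77.05), a mean of 79.45% ± 4.505 (SD, n = 2). The shallow cells of cluster 5 are left out of these shares; counted as epithelial, an alternative chosen after seeing the data, they would bring library 2 to 88.31% and leave library 1 at 82.64%. Basal epithelial-like cells, named from Krt5, Krt14, Krt15, Trp63 and Bcam, were 24.4% and 20.9% of cells. Urethral luminal epithelial-like cells, named from markers such as Krt4, Psca, Ly6d and Krt7, were 22.7% and 15.2%. Fibroblast-like cells were 7.53% and 4.44%, endothelial-like cells 3.87% and 3.04%, and smooth muscle-like cells 2.03% and 0.401%. Macrophage-like cells were 1.13% and 0.965%, T and NK-like cells 0.974% and 0.446%, and B-like cells 0.117% and 0.319%. Skeletal muscle-like cells, named from 3 of 6 markers, were 0.487% and 0.364%, and neuroendocrine-like cells 0.478% and 0.337%. Shares of named classes changed with the cell settings and the clustering. Over 7 alternatives, chosen for these shares after seeing the data, and the main run, luminal-like cells ranged from 2.872% to 27.31% of library 1 and from 15.24% to 38.26% of library 2, basal-like cells from 21.61% to 25.29% and from 14.56% to 20.93%, and macrophage-like cells from 1.074% to 2.346% and from 0.929% to 2.676%. Skeletal muscle-like cells were named in neither library with a mitochondrial share of at most 10% or without doublet removal. With 1 library of each kind, no share was tested between the libraries.

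Cells led by transcripts of the accessory sex glands were grouped apart, although other classes held such transcripts too. Seminal vesicle epithelial-like cells, led by Svs2, Svs4, Svs5 and Svs6, were 5.45% of library 1 and 4.58% of library 2. Prostate secretory epithelial-like cells, named from markers such as Pbsn, Tgm4, Msmb and Defb50, were 0.189% of library 1 (21 cells) and 7.09% of library 2 (779 cells), and fell to 3 and 443 cells with count splitting, 0 and 490 with separate clustering of each library, 6 and 472 with 200 or more genes per cell, and 1 and 379 with a mitochondrial share of at most 10%. In these cells Pbsn, the androgen-regulated prostate protein probasin, was at 2154 CPM in library 1 and 18280 CPM in library 2, whereas Spink1 was at 26140 CPM in library 1 and 1.45 CPM in library 2. Msmb had 0 UMIs in the 21 cells of library 1 and stood at 24500 CPM in library 2. Urothelial umbrella-like cells, with Upk3a at 1970 CPM and Upk2 at 656 CPM, were found as 17 cells of library 2 (0.1547%) and as 0 of 11083 cells of library 1, which allows a share of up to 0.0271%. No cluster was named umbrella-like at resolution 0.5, under separate clustering, with count splitting or at the lower mitochondrial limit. With fewer than 30 cells in library 1, neither the prostate-like nor the umbrella-like class was compared with luminal cells.

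Of the 34 clusters, 11 kept numbers because the fixed markers did not name them. Cluster 1, led by Psca, Sprr1a, Upk2, Clca1 and Snx31, was 2.45% of library 1 and 19.96% of library 2. Clusters 3 and 19, led by Cyp4a12a, Spink8, Pate4, Crisp1 and Lcn2, were 12.9% and 3.45%. Clusters 6 and 26, led by Pip, Prol1, Mup4, Odam and Bglap3, were 9.31% and 1.82%. Cluster 16, led by Fxyd2, Kcne1, Ly6d and Car12, was 1.25% and 1.90%. Cluster 24, led by the proton pump subunits Atp6v1g3 and Atp6v0d2 and by Foxi1, was 1.03% and 0.1547%. Cluster 25, led by Spink11, Crisp1, Akr1b7 and Defb30, was 1.11% and 0.0455%, and cycling cells of cluster 21, led by Top2a and Mki67, were 1.34% and 0.601%. Cluster 17 held immune cells led by Lyz2, Cd74 and H2-Aa, at 1.22% and 1.71%. Cluster 5, led by Hbb-bs (220 of its 223 UMIs in 1 cell), Smr2, 9530053A07Rik and Msmb and with a median of 1144 UMIs per cell in library 2, held 1 cell of library 1 and 1324 cells of library 2 (12.1%) and was placed in no compartment. Several classes came from different clusters in the libraries, as the luminal cells did, most of them from cluster 0 in library 1 and cluster 4 in library 2.

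**Figure D1:**
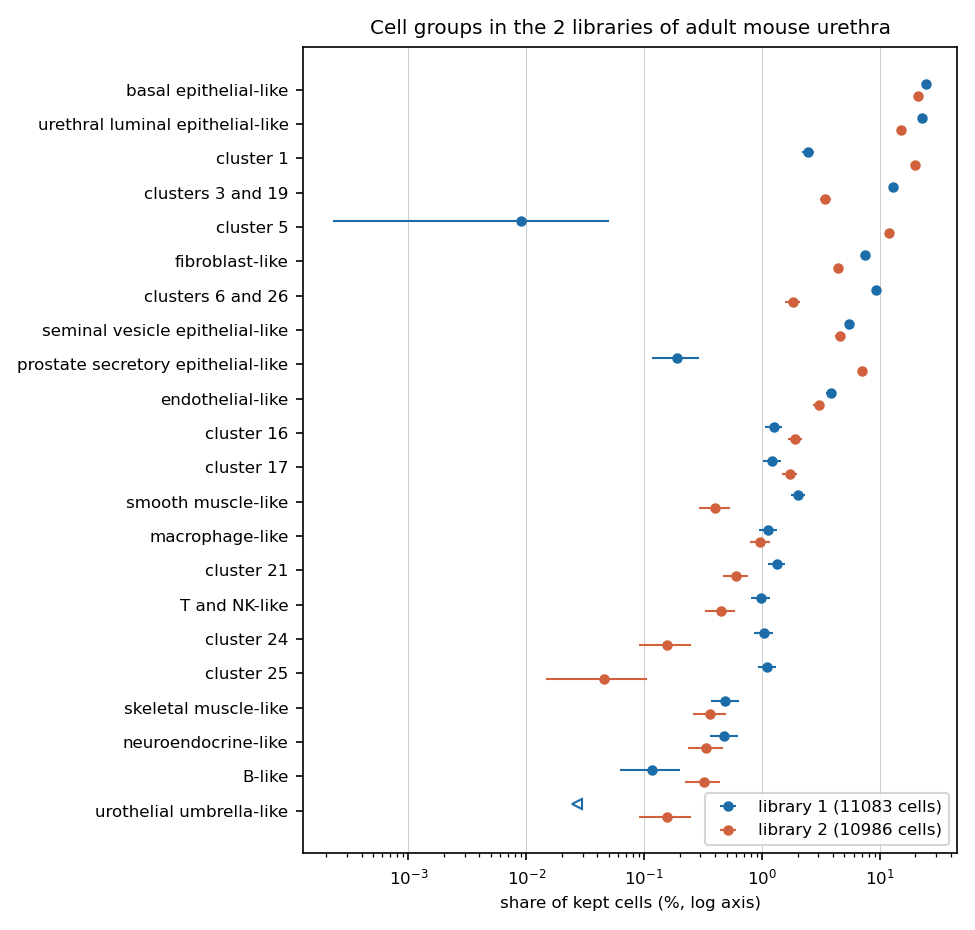
Share of kept cells in each named class or numbered cluster (percent, logarithmic axis) in library 1 (blue) and library 2 (orange), with exact 95% intervals that cover counting error only; the open triangle is the upper limit for umbrella-like cells in library 1. Basal-like cells stand at 24.4% and 20.9%, luminal-like cells at 22.7% and 15.2%, and prostate-like cells stand at 0.189% in library 1 and 7.09% in library 2.

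Luminal-like cells of the urethra, without cluster 1, and basal-like cells differed in adhesion, surface and secretory genes. Col17a1, the transmembrane collagen of hemidesmosomes, was lower in luminal-like cells, at 2.95 CPM in library 1 and 2.15 CPM in library 2, against 98.5 and 81.9 CPM in basal-like cells (log2 fold change -5.29 ± 0.24 SE). Cldn10, a claudin of tight junctions, was higher, at 140 and 306 CPM against 30.8 and 12.1 CPM (3.38 ± 0.21). The mucosal chemokine Cxcl17 (3.40 ± 0.20) and Pigr, the receptor that carries polymeric immunoglobulin across epithelia (3.05 ± 0.21), were higher as well. Igfbp2, which binds insulin-like growth factors, was lower (-5.08 ± 0.22), as was Upk3bl (-5.23 ± 0.25). The adjusted p in edgeR with Benjamini-Hochberg adjustment was 2.0e-104 for Col17a1 and 6.8e-58 for Cldn10. The direction was the same in 2 of 2 libraries, as every call requires. In mm10, Col17a1 lies on chromosome 19 from 47646344 to 47692094, Cldn10 on chromosome 14 from 118787908 to 118875489 and Igfbp2 on chromosome 1 from 72824503 to 72852474.

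Attachment and squamous gene lists leaned toward the basal class. Of 14 hemidesmosome and basement membrane genes, 0 were higher and 7 lower in luminal-like cells, among them the laminin chains Lama3 (-3.77 ± 0.23) and Lamb3 (-3.46 ± 0.21), and 7 were not called. Of 12 squamous and hillock-type genes, 0 were higher and 7 lower, with Anxa8 at -4.24 ± 0.23 and the water and glycerol channel Aqp3 at -3.97 ± 0.21. Lypd3 was also lower (-2.27 ± 0.25), but its direction turned with 200 or more genes per cell (0.45), with a mitochondrial share of at most 10% (0.12), without doublet removal (0.07) and at resolution 0.5 (0.05). Of 8 keratins, 3 were higher, namely Krt23 (2.46 ± 0.28), Krt18 (1.49 ± 0.16) and Krt8 (1.27 ± 0.15), and 3 were lower. Of 18 tight junction and polarity genes, 8 were higher, Cldn3 (1.77 ± 0.18) among them, and only Cldn1 was lower (-4.45 ± 0.28). Of 11 urothelial genes and transcription factors, 2 were higher, Upk1b (1.07 ± 0.17) and Ehf (1.05 ± 0.16), 1 was lower, Upk3bl, and 8 were not called. These counts were the same when adjusted over the list alone.

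Secretory and defence genes split between the classes. Of 11 club-type secretory products, 7 were higher in luminal-like cells, as for Cxcl17 and Pigr, and 2 were lower, including Cp, the plasma ferroxidase ceruloplasmin (-4.23 ± 0.23). Of 6 antimicrobial and oxidant defence genes, 1 was higher, the oxidase subunit gene Cyba (1.60 ± 0.18), and 3 were lower, with Duoxa1 at -4.69 ± 0.29 and Defb1 at -2.25 ± 0.19. Of 8 complement genes, 1 was higher, Cd55 (1.10 ± 0.19), and 4 lower; adjusted over the list alone, 2 were higher and 5 lower. Of 9 MHC class I genes, 1 was higher, Psmb8 (1.17 ± 0.19), and of 6 MHC class II genes 0 were called in either direction. Of 10 xenobiotic and redox enzymes, 1 was higher, Cbr2 (1.27 ± 0.14), and 4 lower, among them the aldehyde dehydrogenase Aldh3a1 (-2.70 ± 0.20) and Adh7 (-2.31 ± 0.20). Except for complement, the counts were the same when adjusted over the list alone.

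In the chemokine, growth factor and Notch lists, every call was lower in luminal-like cells. The chemokine Cxcl17, which was higher, is counted in the club-type secretory list instead. Of 9 chemokines and cytokines, 0 were higher and 5 lower in luminal-like cells, with Cxcl12 at -3.80 ± 0.22, the alarmin Il33 at -2.74 ± 0.19 and Csf1 at -1.30 ± 0.21. Of 21 growth factors and receptors, 0 were higher and 6 lower, or 7 when adjusted over the list alone, with Igfbp5 at -2.12 ± 0.16 and Pdgfa at -1.99 ± 0.18. Of 12 Notch pathway genes, 0 were higher and 4 lower, with the ligands Jag2 (-4.18 ± 0.22) and Jag1 (-1.30 ± 0.19) and the glycosyltransferase Lfng (-1.67 ± 0.24). Of 10 progenitor-associated genes, 4 were higher, with Prom1 at 2.49 ± 0.19 and Cd44 at 2.17 ± 0.19, and 2 were lower, with Itga2 at -1.22 ± 0.21. Of 16 androgen-responsive genes, 5 were higher, with Slc45a3 at 1.87 ± 0.20, and 3 lower, with Ndrg1 at -3.62 ± 0.24 and Sord at -2.88 ± 0.20. Of 9 retinoid pathway genes, 1 was higher, Aldh1a3, which makes retinoic acid (1.42 ± 0.21), and 3 lower, with Cyp26b1, which degrades it, at -1.90 ± 0.20. Of 19 immediate early and heat shock genes, 1 was higher and 2 lower, and of 14 HOX genes, 1 was higher and 1 lower. The lower HOX gene was Hoxb8 (-1.59 ± 0.22), whose direction turned when cluster 11 was left out of the basal class (0.20), an alternative chosen after seeing the data. Cluster 11 is led by Apoe, Trem2, Mia and Cxcl12, with Cp also among its 10 leading genes and none of the basal markers. Without it Cxcl12 (-2.19) and Cp (-3.14) were still called at smaller differences, and Upk1b (0.97) and Cd55 (0.93) were no longer called. Apart from growth factors, these counts were the same when adjusted over the list alone.

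In all, 848 genes were higher and 1222 lower in luminal-like than in basal-like cells, of 13053 tested in edgeR. The count of 2070 fell to 251 with no replicate block and to 1124 with all classes in 1 fit. Each of the 251 genes was also called with the block, and its direction could not differ because the same sums were used. Luminal-like cells came mostly from cluster 0 in library 1 and cluster 4 in library 2. Basal-like cells came mostly from cluster 2 in library 1 and clusters 7 and 8 in library 2. The leading genes of cluster 7 include Sprr1a, Upk3bl, Aqp3, Aldh3a1 and Krt4. The luminal class left out cluster 1, which had 5 of 5 luminal markers counted and was 19.96% of library 2. Cluster 1 held less Cldn10 and Cd44 than luminal-like cells. With cluster 1 counted as luminal, an alternative chosen after seeing the data, 1912 genes were called. Of the named genes, 41 kept their call, 5 lost it and 0 reversed.

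**Figure D2:**
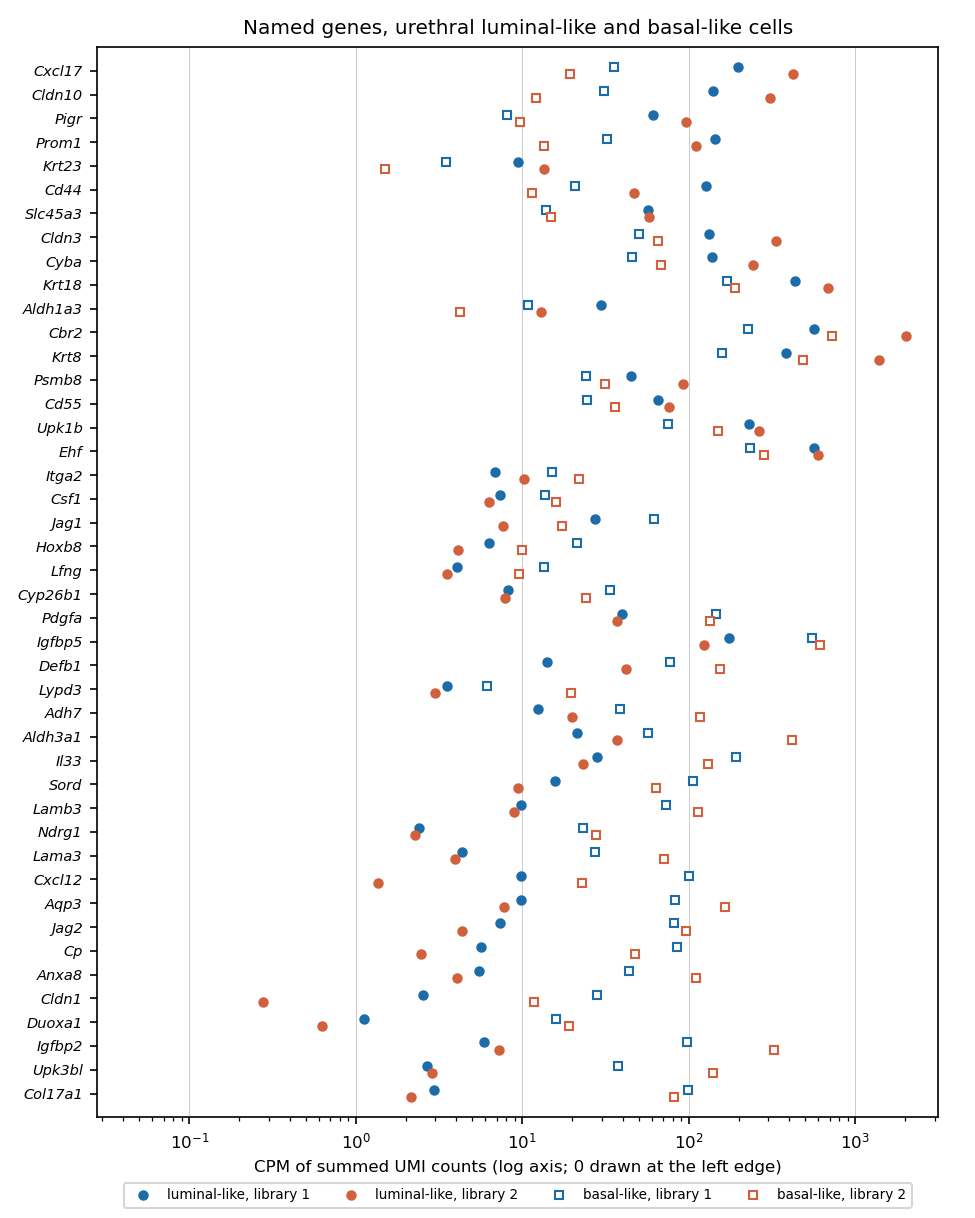
CPM of summed UMI counts (logarithmic axis) of genes named by the fixed rule in luminal-like cells (filled circles) and basal-like cells (open squares), each point 1 library, library 1 in blue and library 2 in orange. Col17a1 stands at 2.95 and 2.15 CPM in luminal-like cells and at 98.5 and 81.9 CPM in basal-like cells.

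Fibroblast-like and smooth muscle-like cells were separated by contractile genes on the muscle side and by matrix, complement and Wnt genes on the fibroblast side. Tagln, the actin-binding protein transgelin, stood at 46.2 and 20.6 CPM in fibroblast-like cells of libraries 1 and 2 and at 2721 and 6849 CPM in smooth muscle-like cells (log2 fold change -7.35 ± 0.19 SE). Wif1, a secreted inhibitor of Wnt ligands, was higher in fibroblast-like cells, at 437 and 990 CPM against 13.2 and 10.9 CPM (5.70 ± 0.31). Cd34 (4.89 ± 0.31) and the matrix genes Col15a1 (4.54 ± 0.31) and Fbln1 (303 and 457 CPM against 21.2 and 10.9 CPM) were higher too. The adjusted p in edgeR with Benjamini-Hochberg adjustment was 6.2e-293 for Tagln and 8.6e-70 for Wif1. Each kept its direction in 2 of 2 libraries, as every call requires. In mm10, Tagln lies on chromosome 9 from 45929619 to 45936058 and Wif1 on chromosome 10 from 121033960 to 121100650.

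Every one of the 17 contractile genes tested was lower in fibroblast-like cells, also when adjusted over the list alone. The muscle class was itself named from contractile markers such as Acta2 and Myh11, so this list partly restates how the class was defined. Pln, the phospholamban that restrains the calcium pump of muscle, had 1 UMI in fibroblast-like cells and 458 in smooth muscle-like cells, a ratio of 2540 in favour of muscle (95% counting interval 453.6 to 100500). Of 9 Notch pathway genes, 0 were higher in fibroblast-like cells and 4 lower, with Notch3 at -4.35 ± 0.32, Nrarp at -3.59 ± 0.41 and Heyl at -1.90 ± 0.33. Of 19 collagens and matrix proteins, 13 were higher and 1 lower, and Fbln2 had 1 UMI in muscle cells, a ratio of 40.4 (7.17 to 1602). Of 11 matrix proteases and inhibitors, 8 were higher and 1 lower, with Mmp2 at 6.07 ± 0.39, and Serpinf1, which had 3 UMIs in muscle cells, at a ratio of 146 (49.9 to 708). These counts were the same when adjusted over the list alone.

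Complement, chemokine and regional genes were mostly on the fibroblast side. Of 9 complement genes, 8 were higher and 0 lower, also when adjusted over the list alone, and C3, the central complement component, had 1 UMI in muscle cells, a ratio of 87.1 (15.6 to 3447). Of 14 fibroblast regional and subtype genes, 12 were higher and 2 lower under either adjustment, and the estrogen sulfotransferase Sult1e1, with 0 UMIs in muscle cells, was at least 8.17-fold higher. Of 9 chemokines and cytokines, 6 were higher, or 7 when adjusted over the list alone, and 1 was lower. Ccl2, with 0 UMIs in muscle cells, was at least 6.73-fold higher, and Cxcl14 was higher by a log2 fold change of 3.37 ± 0.30. Of 11 Wnt pathway genes, 7 were higher, or 8 when adjusted over the list alone, with Wnt2 at 3.87 ± 0.47, Wnt6 at 2.66 ± 0.59 and Sfrp2 at 1.86 ± 0.20, and 0 were lower. Of 19 growth factors and receptors, 8 were higher, with Igf1 at 3.86 ± 0.41 and Igfbp6 at 3.25 ± 0.22, and 2 lower, with Hbegf at -4.10 ± 0.59, under either adjustment.

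BMP and TGF-beta pathway genes went both ways. Of 18 BMP and TGF-beta pathway genes, 4 were higher in fibroblast-like cells, with Bmp4 at 3.58 ± 0.36, and 3 lower, or 4 when adjusted over the list alone, with the activin subunit Inhba at -3.21 ± 0.42 and Chrdl1 at -3.44 ± 0.52. Of 7 MHC class I genes, 4 were higher and 0 lower, with Tapbp at 2.00 ± 0.28 and H2-D1 at 1.70 ± 0.23, and of 2 MHC class II genes 0 were called. Of 15 immediate early and heat shock genes, 5 were higher and 0 lower, with Klf4 at 1.83 ± 0.36 and Jun at 1.48 ± 0.32. Of 5 steroid receptors and enzymes, 2 were higher and 0 lower, and Hsd11b1, which regenerates active glucocorticoid, had 0 UMIs in muscle cells and was at least 24.3-fold higher. Of 10 HOX genes, 2 were higher, Hoxd11 (1.88 ± 0.46) and Hoxd13 (1.80 ± 0.43), and 8 were not called. Apart from the BMP and TGF-beta list, these counts were the same when adjusted over the list alone.

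In all, 799 genes were higher and 688 lower in fibroblast-like than in smooth muscle-like cells, of 8295 tested in edgeR. The count of 1487 fell to 661 with DESeq2, to 496 with no replicate block and to 988 with count splitting. Library 2 contributed 44 smooth muscle-like cells, and fibroblast-like cells came mostly from cluster 9 in library 1 and cluster 15 in library 2.

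**Figure D3:**
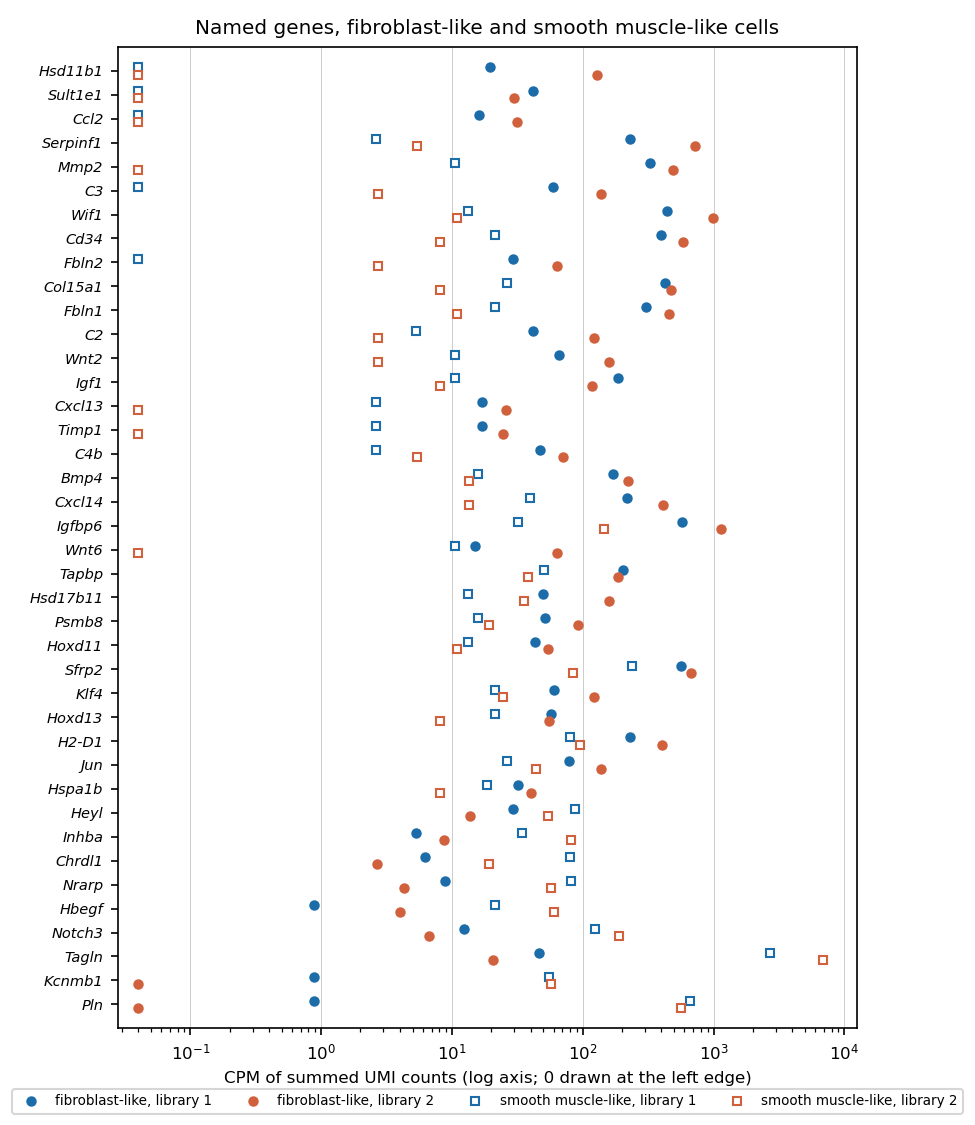
CPM of summed UMI counts (logarithmic axis, 0 at the left edge) of the genes named by the fixed rule in fibroblast-like cells (filled circles) and smooth muscle-like cells (open squares), each point 1 library, library 1 in blue and library 2 in orange. Tagln stands at 46.2 and 20.6 CPM in fibroblast-like cells and at 2721 and 6849 CPM in smooth muscle-like cells.

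Within the fibroblasts, the larger of the compared sub-clusters carried more Wif1 and Wnt2 than the smaller, and every called complement and matrix gene was higher in the smaller. Wif1 and Wnt2 are also among the leading genes of sub-cluster 4, which was not compared, so they do not mark the larger sub-cluster alone. Sub-cluster 0 held 687 cells of library 1 and 161 of library 2, and sub-cluster 1 held 56 and 102. Wif1 was higher in sub-cluster 0, at 413 and 502 CPM against 13.2 and 6.14 CPM (log2 fold change 6.07 ± 0.45 SE, adjusted p = 5.0e-09 in edgeR with Benjamini-Hochberg adjustment), as was Wnt2 (3.23 ± 0.46). C3 was lower there, at 15.8 and 44.5 CPM against 673 and 540 CPM (-4.25 ± 0.33), and so were the antioxidant enzyme gene Gpx3 (-4.66 ± 0.34) and Igf1 (-2.50 ± 0.29). Sult1e1 had 3 UMIs in sub-cluster 0 and 115 in sub-cluster 1, a ratio of 94.2 in favour of sub-cluster 1 (31.4 to 464), and Cxcl13, a B cell chemoattractant, had 2 and 79, a ratio of 97.1 (26.0 to 816). Each of these genes went in the same direction in 2 of 2 libraries, as every call requires.

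Most calls in the gene lists were lower in sub-cluster 0. Of 20 collagens and matrix proteins, 0 were higher and 8 lower in sub-cluster 0, with Col6a3 at -4.03 ± 0.43, Fbln2 at -2.78 ± 0.39 and Col14a1 at -2.03 ± 0.33. Of 9 chemokines and cytokines, 2 were higher, with Cxcl12 at 1.74 ± 0.31, and 3 lower, with Ccl11 at -3.93 ± 0.48, or 2 and 5 when adjusted over the list alone. Of 14 regional and subtype genes, 1 was higher and 4 lower, or 2 and 6 over the list alone. Of 9 complement genes, 0 were higher and 3 lower, with Cd55 at -2.49 ± 0.34, or 1 and 4 over the list alone. Wnt2 was the only call among 10 Wnt genes, with 3 higher over the list alone. Of 19 growth factors and receptors, 1 was higher, Fgfr2 (1.56 ± 0.37), and 2 lower, with Igfbp5 at -1.91 ± 0.26. Of 11 matrix proteases and inhibitors, 2 were lower, Adamts5 (-1.83 ± 0.41) and Serpinf1 (-1.44 ± 0.30), and of 4 steroid receptors and enzymes 1 was lower, Hsd11b1 (-1.51 ± 0.34). Over the list alone these last 3 lists kept their counts.

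Across all genes, 0 were called in edgeR among 14 contractile, 7 Notch, 17 BMP and TGF-beta, 8 MHC class I, 4 MHC class II, 16 immediate early and heat shock, and 10 HOX genes. Adjusted over the list alone, 1 contractile and 1 HOX gene were higher, and 1 immediate early gene was higher and 1 lower. In all, 32 genes were higher and 72 lower in sub-cluster 0, of 8476 tested. With no replicate block 0 genes were called (209 of all 8476 had an unadjusted p under 0.05), DESeq2 called 38, and with all classes in 1 fit 24 were called. With a mitochondrial share of at most 10%, where the largest sub-clusters hold other cells, 1 of the 104 genes was called in the same direction and 27 in the other.

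For the signalling lists, each gene was given to a class only where that class led clearly in both libraries. Of 147 genes, 88 reached 20 CPM in the leading class of each library and 25 were given to a class, 10 of them to fibroblast-like cells. Fibroblast-like cells led for the chemokine Cxcl12 (779 and 658 CPM in libraries 1 and 2), for Igfbp6 (578 and 1148 CPM), Sfrp2 (565 and 675 CPM), Wnt5a (252 and 211 CPM) and Wnt2 (65.8 and 158 CPM), and for Ltbp4 (884 and 961 CPM). Fstl1, Vegfa, Cxcl14 and Aldh1a3 were also given to them. Macrophage-like cells led for Cxcl16 (496 and 579 CPM) and for the leukotriene and prostaglandin pathway genes Alox5ap (177 and 153 CPM) and Hpgds (157 and 224 CPM), and also for Plcb2. Neuroendocrine-like cells led for the serotonin pathway genes Tph1 (409 and 486 CPM), Slc18a1 (126 and 58.5 CPM) and Ddc (70.8 and 23.8 CPM).

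Basal-like cells led for Il33 (191 and 130 CPM) and Igfbp2 (96.9 and 326 CPM), and endothelial-like cells for Igfbp3 (649 and 473 CPM). Smooth muscle-like cells led for Ccl11 (71.5 and 95.4 CPM), Rbp4 (71.5 and 79.0 CPM) and Inhba (34.4 and 81.8 CPM). Skeletal muscle-like cells, whose 10 leading genes include Meg3, Chodl and Peg3 and none of the class markers, led for Hoxc9 (73.8 and 58.7 CPM) and Hoxc10 (52.7 and 106.5 CPM). By list, 6 chemosensory and mechanosensory genes, 5 chemokines and cytokines, 4 growth factors and receptors, 3 Wnt, 3 BMP and TGF-beta, 2 retinoid and 2 HOX genes were given to a class, and 0 of 9 steroid receptors and enzymes were. When numbered clusters counted as classes, an alternative chosen after seeing the data, Aldh1a3, Alox5ap and Plcb2 were no longer given to these classes. With a mitochondrial share of at most 10%, 17 of the 25 genes kept their class, and Inhba, Ccl11, Rbp4, Hoxc9, Hoxc10, Tph1, Ddc and Slc18a1 did not. Without doublet removal Igfbp2 was lost, and so were Hoxc9 and Hoxc10, as no cluster was then named skeletal muscle-like. At resolution 0.5 Ccl11, Rbp4 and Plcb2 were lost, at resolution 2 Plcb2, and with 200 or more genes per cell Igfbp2 and Plcb2. With library 2 alone 45 genes were given to a class, since a single library then sets the rule.

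The libraries differed in gland and other transcripts within every class compared. Over 9110 genes in 6 classes, 12 were higher in library 2 and 37 in library 1 by 4-fold or more in every class. With counts under 3 set to 3, the 5 genes with the largest median log2 ratio of library 2 over library 1 were Pbsn (8.06), Defb50 (7.64), Msmb (7.49), 9530053A07Rik (7.42) and Gm42418. Library 1 held fewer than 3 UMIs of Pbsn in 4 of the 6 classes and of Msmb in all 6, so their values are lower bounds and the order of these genes is not settled. In fibroblast-like cells, Pbsn stood at 1.78 CPM in library 1 and 759 CPM in library 2. On the side of library 1 were the hemoglobin genes Hbb-bs (-6.43), Hba-a1 (-5.61) and Hba-a2 (-5.05), the prostate gene Sbp (-6.14) and the seminal vesicle gene Svs2 (-6.01). Library 2 held fewer than 3 UMIs of Hbb-bs in 3 of the 6 classes, of Hba-a1 in 3, of Hba-a2 in 6 and of Sbp in 4, so the size and order of these ratios are not settled either. Svs2 stood at 115500 CPM in seminal vesicle epithelial-like cells of library 1 and at 1218 CPM in those of library 2. Gland cells here are the seminal vesicle-like and prostate-like classes. Clusters 3 and 19, clusters 6 and 26 and cluster 25 were also counted as gland, although the fixed markers did not name them. Of the 12 genes higher in library 2, 7 had their highest level in these cells, far above the median group. So did 12 of the 37 higher in library 1, of which Prol1, Pip, Bglap3, Mup20 and Wfdc18 lead cluster 6 and Spink11 leads cluster 25. The number for library 1 therefore rests partly on unnamed clusters. The other 5 genes higher in library 2 were Gm42418 (median log2 ratio 7), AY036118 (6.966), Lars2 (3.938), mt-Nd3 (2.874) and mt-Nd2 (2.175). Library 1 held fewer than 3 UMIs of AY036118 in 3 of the 6 classes and of Lars2 in 1, so the size of their ratios is not settled. What set these genes apart was not tested. All values are ratios of single libraries with no replicate of either, so no test was made. The mice and the depth differ between the libraries, and which kit each used is not known. In mm10, Pbsn lies on chromosome X from 77837901 to 77853623 and Svs2 on chromosome 2 from 164235929 to 164238466.

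**Figure D4:**
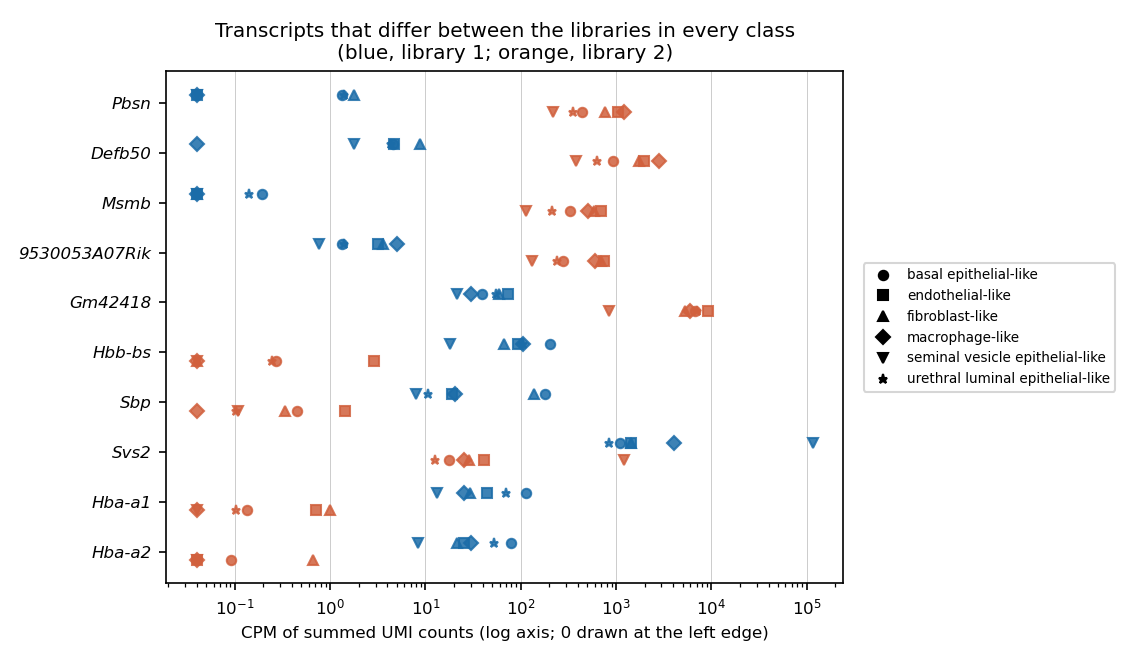
CPM of summed UMI counts (logarithmic axis, 0 at the left edge) of the 5 transcripts with the largest median ratio in each direction, in 6 classes (symbols) of library 1 (blue) and library 2 (orange). Pbsn in fibroblast-like cells stands at 1.78 CPM in library 1 and 759 CPM in library 2, and each transcript keeps its direction in all 6 classes.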

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

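The tests chosen only after the result was seen are those on cluster 1, neuroendocrine-like and seminal vesicle epithelial-like cells, cluster 1 counted as luminal, basal cells without cluster 11, for the class map the numbered clusters and each library left out, for the epithelial share count splitting and cluster 5 counted as epithelial, and every alternative for the shares of named classes. Both classes of each comparison come from the same animals, so library was used as a block in the pairing of classes. With no replicate block, calls fell from 2070 to 251 for luminal against basal, from 1487 to 496 for fibroblast against smooth muscle, from 1127 to 446 for neuroendocrine against luminal and from 2383 to 952 for seminal vesicle against luminal. All the calls left in these 4 comparisons were also called with the block. Their direction could not differ, because both runs used the same sums and a call requires the same direction in both libraries. Without the block, edgeR called 0 genes for the sub-clusters, against 104, and 0 for cluster 1 against luminal, against 948; of all genes tested, 209 of 8476 and 797 of 12831 had an unadjusted p under 0.05. With all classes in 1 fit, calls were 1124 for luminal against basal, 24 for the sub-clusters and 476 for cluster 1. DESeq2 called 661 genes for fibroblast against smooth muscle, 38 for the sub-clusters, 368 for cluster 1 and 538 for neuroendocrine cells. Count splitting gave 988 for fibroblast against smooth muscle and 583 for neuroendocrine cells. The cause was not tested.

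The sub-cluster result also changed with how cells were chosen and clustered. Calls rose to 170 with a mitochondrial share of at most 10%, 180 at resolution 0.5, 162 at resolution 2 and 197 with count splitting. The 2 largest sub-clusters are then other sets of cells: of the 104 genes, 94 and 103 were called in the same direction at resolutions 0.5 and 2, but 28 with 200 or more genes per cell (1 in the opposite direction), 10 with count splitting (23 opposite), 4 without doublet removal (11 opposite) and 1 with the lower mitochondrial limit (27 opposite). Lypd3 reversed in luminal against basal, to a log2 fold change of 0.4454 with 200 or more genes, 0.123 with the lower mitochondrial limit, 0.07383 without doublet removal and 0.05132 at resolution 0.5. Hoxb8 reversed to 0.2017 without cluster 11. Olfm4 reversed to 0.799 in neuroendocrine against luminal cells without doublet removal. The cause of these reversals was not tested.

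With 1 library left out, the called genes that kept a 2-fold difference in the same direction in the other library were 1418 to 1460 for luminal against basal, 1245 to 1383 for fibroblast against smooth muscle, 92 to 93 for the sub-clusters, 560 to 680 for cluster 1, 1004 to 1007 for neuroendocrine cells and 1942 to 1997 for seminal vesicle cells. These genes had been called with both libraries in the same direction, so their direction was fixed. No gene was selected or tested anew, so these counts are not separate evidence. With 1 library left out, the class map gave 37 to 45 genes to a class, against 25 with both libraries. The epithelial share was then 76.26% to 82.63%. With the shallow cluster 5 counted as epithelial, the mean share rose from 79.45% to 85.48%, and library 2 (88.31%) then stood above library 1 (82.64%). Of 7 alternatives, the mean share moved by more than the spread between libraries in 7 for macrophage-like cells, 5 for luminal-like, 3 for skeletal muscle-like, 2 for basal-like, 1 each for endothelial-like, seminal vesicle-like, neuroendocrine-like, B-like and T and NK-like cells, and 0 for the other classes, among them the prostate-like and umbrella-like cells, whose counts still changed as the report states. In the alternatives that could be run, other counts of calls stayed within 1.5 times the reported count. Single genes could still lose their call. Of those named by the rule for luminal against basal, 37 kept it with 200 or more genes per cell, 8 lost it and 1 reversed. Count splitting lost 7, no doublet removal 6 and resolution 0.5 also 6. Fibroblast against smooth muscle was not run at the lower mitochondrial limit (10 muscle cells in library 2), nor were neuroendocrine cells there (16 cells) and under separate clustering (22 cells). Sub-clusters were not run under separate clustering, and prostate-like or umbrella-like cells in no setting. Cluster 1 was not run under other cell settings, other resolutions, separate clustering or count splitting. Depth limits library 1, where the median kept cell held 2039 UMIs against 9433 in library 2.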

Other observations

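The comparisons of cluster 1, neuroendocrine-like and seminal vesicle epithelial-like cells with luminal cells were chosen only after the classes were seen, as were the tests on gland transcripts other than Sbp, on Sbp in doublets and without its top cells, on genes without an overlapping gene and on free RNA in cluster 5. Cluster 1 carried more squamous and detoxifying transcripts than urethral luminal epithelial-like cells, and more Upk3b and Upk3bl. Cluster 1 also had 5 of 5 luminal markers counted, with Psca and Krt4 leading. Clusters 0 and 4, which hold most luminal-like cells of libraries 1 and 2, had 4 of 5 each, and Cldn10 is a leading gene of cluster 4. The umbrella markers Upk2, Upk1a and Snx31 among the 10 leading genes of cluster 1 kept it unnamed. Sprr1a also led, so its uroplakin and squamous values partly restate why cluster 1 was compared. Upk3b was higher, at 13.2 and 56.7 CPM in libraries 1 and 2 against 0.985 and 2.92 CPM (log2 fold change 4.38 ± 0.20 SE), as were Aqp3 (46.9 and 64.9 CPM against 9.85 and 7.78 CPM) and Aldh3a1 (2.75 ± 0.15). Cldn10 (-4.65 ± 0.18), Cd44 (-3.38 ± 0.18) and Prom1 (-2.20 ± 0.15) were lower. Of 11 urothelial genes 4 were higher and 0 lower, of 11 squamous and hillock-type genes 5 and 0, of 10 xenobiotic enzymes 5 and 1, and of 9 progenitor-associated genes 0 and 4, and these counts were the same when adjusted over the list alone. Of 12831 genes tested in edgeR, 421 were higher and 527 lower, and with no replicate block 0 were called (797 of all 12831 had an unadjusted p under 0.05).

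Neuroendocrine-like cells (53 and 37 cells) carried the serotonin pathway transcripts Tph1, Slc18a1 and Ddc. Of 8 chemosensory and mechanosensory genes, the list these belong to, 3 were higher and 0 lower, with a median log2 fold change of -1.099. Tph1, the enzyme that starts serotonin synthesis, stood at 409 and 486 CPM in libraries 1 and 2, against 0 and 0.278 CPM in luminal-like cells (10.92 ± 0.37). Slc18a1 (6.55 ± 0.56) and Ddc (5.53 ± 0.70) were higher too, as were Igfbp5 (3.52 ± 0.31), Aldh1a2 (7.18 ± 0.76), Hoxb8 (3.54 ± 0.42) and the Notch ligand Dll1 (4.11 ± 0.96). Of 10 Notch pathway genes 3 were higher and 2 lower, and of 17 growth factors and receptors 2 were higher and 1 lower, or 2 lower when adjusted over the list alone. Fgf10 had 2 UMIs in luminal-like cells, a ratio of 506 (95% counting interval 122 to 4479). Of 10 club-type secretory products 0 were higher and 6 lower, with Cxcl17 at -2.59 ± 0.30 and Clu at -2.14 ± 0.33, also when adjusted over the list alone. In all 761 genes were higher and 366 lower of 11199 tested in edgeR, a count that fell to 446 calls with no replicate block and 538 with DESeq2.

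Seminal vesicle epithelial-like cells differed from luminal-like cells in HOX and retinoid genes. Hoxb8 was higher, at 33.9 and 90.8 CPM against 6.33 and 4.13 CPM (4.87 ± 0.44), and Hoxa13 (-3.81 ± 0.34) and Hoxd13 (-3.49 ± 0.28) were lower. Of 14 HOX genes 5 were higher and 7 lower, and of 9 retinoid pathway genes 1 was higher and 8 lower, with Stra6 at -3.28 ± 0.43 and Aldh1a3 at -2.65 ± 0.45. The counts for both lists were the same when adjusted over the list alone. Lcn2 (5.18 ± 0.27) was the only one higher of 11 club-type secretory products, with 7 lower, and B2m (4531 and 6641 CPM against 678 and 550 CPM) the only one higher of 9 MHC class I genes, with 1 lower, or 0 when adjusted over the list alone. Of 4 antimicrobial and oxidant defence genes 1 was higher and 2 lower. Foxa1 (-2.66 ± 0.24), Klf5 (-2.71 ± 0.26) and Sox2 (-3.11 ± 0.34) were lower. In all 790 genes were higher and 1593 lower of 12303 tested in edgeR, and 952 calls were left with no replicate block.

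Gland transcripts, led by gland cells as defined above, were found in every class of the library that had more of them. No biological explanation was tested, since the design has 1 group. Free RNA of gland cells predicts fixed ratios between transcripts in classes that are not gland, and for the 7 of library 2, such as Pbsn and Defb50, the largest of 30 ratios departed 1.94-fold from its median, within the 2-fold set for it. Doublets would confine transcripts to few cells. Only pairs of transcript and class with an expected share neither very low nor very high entered. This left out Pbsn and Defb50 of library 2 and Prol1 and Esp8 of library 1. Over the pairs that entered, the median share of cells with the transcript was 1.01 of that under even spreading in library 2 and 0.897 in library 1. This argues against doublets as the main source of the transcripts measured. In macrophage-like cells, though, Azgp1 of library 2 (0.33) and Gm17689 of library 1 (0.233) were confined to few cells. Single cells also held much of other transcripts: 1 macrophage-like cell held 545 of 810 Svs2 UMIs in library 1, and in library 2 another held 802 of 1666 Defb50 UMIs and 1 fibroblast-like cell 985 of 2081 9530053A07Rik UMIs. The ratios include such cells, for which doublets stay open. In library 1 the largest departure was 11.4-fold, for Sbp in basal-like cells, where 1 cell held 832 of 935 UMIs, and without the top cell of each class Sbp departed by up to 2.13-fold. Sbp stood at 0.167 of even spreading because of such single cells, so doublets and gland cells placed in another class cannot be told apart there, and the other transcripts of library 1 departed by up to 2.81-fold, at 9 UMIs of Gm17689, which leaves free RNA open.

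Another 25 genes higher in every class of library 1 were not led by gland cells. Reads shared with a gene that overlaps on the same strand, such as for Nme2 and Tomm6, predict more overlaps among them. Of these genes 24% (6 of 25) overlapped, against 5.34% of the 9072 other genes compared that could be matched to GENCODE vM21 (two-sided Fisher exact p = 0.00174). The other 19 genes, with Hbb-bs, Hba-a1 and Hba-a2 among them, overlap no gene on the same strand in GENCODE vM21, so this explanation does not reach them there. They were split off by that lack of overlap, so their number is not separate evidence. The submitters' annotation is not known, and why an overlap would act in 1 library only was not tested. What set these 19 apart stays open, and mice and depth differ between the libraries at the same time. No biological explanation was tested.

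Cluster 5 held 1324 shallow cells of library 2, with a median of 1144 UMIs against 9433 in all its kept cells. Droplets with mostly free RNA would carry gland transcripts at 5-fold or more of the level in classes that are not gland, and the median fold was 4.07, between the bounds set. The fold is of CPM, so an equal amount of free RNA per droplet would raise it in any shallow group. Msmb and 9530053A07Rik, which entered it, are also leading genes of cluster 5. The fold therefore cannot decide what these droplets hold. Prol1, Pip, Smr2 and 2310057J18Rik also lead cluster 5. They lead clusters 6 and 26 as well, whereas Msmb and 9530053A07Rik lead the prostate-like cluster 14. Whether single droplets hold transcripts of both was not tested. Damaged cells would have a mitochondrial share of 1.5 times or more that of kept cells, and the ratio was 1.16 (9.83% against 8.48%), also between the bounds. Free RNA and damage therefore cannot be told apart here, and no biological explanation was tested.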
